A study of Homo sapiens with 14 samples.

How the data were processed

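The series compared HTR8/SVneo cells, an immortalized invasive trophoblast line of the human first-trimester placenta, that carried a control short hairpin RNA (shNC) with cells that carried one against METTL3, the catalytic subunit of the nuclear N6-methyladenosine (m6A) RNA methyltransferase. Per the labels' protocols, the cells received 30 mM glucose for 24 h; the protocol is given with the m6A-seq samples, and for the other samples it was taken from the description of the whole series. The 14 samples fall into 3 assays. In m6A-seq, fragmented total RNA was precipitated with an antibody against m6A, with 2 control and 2 knockdown libraries. Input RNA is the same kind of fragmented RNA before precipitation, also 2 against 2. RNC-seq, 3 against 3, reads RNA bound to ribosomes with a nascent protein chain: cells were held in cycloheximide, which stalls elongating ribosomes, and the complexes were pelleted through sucrose. Per the labels' protocols, the m6A-seq libraries were made with a stranded total RNA kit (SMARTer) and the RNC libraries with NEBNext Ultra, so a direct ratio of RNC to input reads mixes ribosome loading with the kits.

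For input RNA and RNC RNA the deposited values are raw read counts per gene in 10 libraries, with no normalization by the authors. Per the file headers, the authors counted reads on exons of a GENCODE annotation with featureCounts 1.6.4, without the options for strand, read pairs or multi-mapping reads; per the submitters' processing notes, the version was 2.0.0. Sense and antisense reads were therefore counted together, and reads that aligned to several places, as in near-identical gene copies, were left out. Per the submitters' processing notes, reads were trimmed with cutadapt and Trim Galore, checked with FastQC and aligned to hg19 with Subread 2.0.0. The count tables hold 45320 genes, of which 14014 have only an Ensembl identifier and 22115 matched a symbol or synonym in the RefSeq gene table; 30 genes had exons on 2 chromosomes. Total counts per library ranged from 31474489 to 42115944.

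For the precipitated libraries the deposited values are peaks that the authors called with MACS2, per the submitters' processing notes, in hg19 coordinates. There is 1 list for each library and 1 pooled list for each genotype. Each deposited peak has a fold enrichment ratio, a −log10 q-value and a summit position as the peak caller writes them. The lowest −log10 q in the deposited pooled lists was 1.3. The calling parameters, the control sample and the read depth of these libraries are not given in the sources used here, so differences in sensitivity between the lists could not be measured. A table of counts by gene symbol was not used here because the tables for single samples hold the same kind of counts with exon coordinates. The test of m6A enrichment per gene was not run because no counts of the precipitated libraries are among the deposited tables, and sequence motifs at peaks were not examined because an hg19 genome was not used here.

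Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, libraries were scaled with TMM factors, and quasi-likelihood tests (glmQLFit and glmQLFTest, two-sided) were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 5% false discovery rate (FDR). RNC libraries (14281 genes) and input libraries (18528 genes) were fitted separately. The RNC response relative to the input response, called the translation ratio, was tested as an interaction in 1 model over all 10 libraries (19827 genes). A kit effect that multiplies the counts of a gene alike in both genotypes cancels in that contrast. RNA that mainly 1 assay captures does not cancel, so a change of the ratio need not be a change of ribosome loading. Levels are given as CPM, counts scaled to a common library size with the TMM factors, and errors given with CPM are SDs between libraries. Standard errors of log2 fold changes (SE) come from the fitted model.

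Gene lists (33 lists of pathways, complexes and cell type markers) were tested with camera in limma 3.58.1 on voom-weighted log counts, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists with at least 5 tested members. The same test with the correlation estimated from the data stands beside each call. For the called lists the preset correlation gave the smaller p-values, and for the m6A-lost and m6A-kept genes the larger ones. The version with an estimated correlation also rests on the few residual degrees of freedom of the libraries. For cytotrophoblast markers in input RNA that correlation was −0.063, below the preset, yet the camera p went from 5.62e-05 to 0.0504. A call lost with it therefore does not by itself show correlation between genes. A second test in limma, fry, asked whether the members changed in a shared direction, without comparing them with other genes. Its p-values were adjusted by the Benjamini-Hochberg method over the same lists. Changes in opposite directions can cancel in fry, so a list that did not pass it may still hold changed members. Members past 5% FDR were counted over all genes tested and adjusted over the list alone.

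Peaks were compared with bedtools 2.31.1 and an overlap of at least 1 bp. A reproducible peak is a peak of replicate 1 that overlaps a peak of replicate 2 of the same genotype. A gene was called m6A-lost where a reproducible control peak lay on its exons and no peak of either knockdown library did, and m6A-kept where reproducible peaks of both genotypes lay on its exons. Both classes were tested against all other genes with camera. Fisher's exact test, two-sided, compared the share of each list's genes with a reproducible control peak on exons with that of all genes tested in input RNA. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the peaks.

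The genes named are METTL3, then the 10 largest rises and 10 largest falls past 5% FDR among named genes with a mean log2 CPM of at least 4 whose knockdown libraries all lie on 1 side of the control libraries (for the translation ratio, whose RNC change has the same sign). Ribosomal RNA, mitochondrial and small non-coding genes were left out of that ranking. Up to 4 members of each list with the smallest p were added. For m6A, the 10 lost and 10 kept genes with the highest fold enrichment in the authors' pooled control list and the genes of the m6A pathway were taken. The tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined; genes named outside the rule were chosen after their values were seen. No Y-linked gene or XIST is reported.

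The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, other filters on low counts, all libraries in 1 fit, the replicate number as a block, libraries without mitochondrial, ribosomal RNA and histone genes, each library left out in turn, stricter peak thresholds, other overlaps and peak assignments, the authors' pooled lists, and matched reference genes. Counts were simulated with the means and library sizes of these data, with changes planted only in genes of an average log2 CPM above 2. Recovery among weaker genes was not measured. In the RNC comparison edgeR recovered 87% of 2-fold and 100% of 4-fold changes. The recoveries were 45% and 72% in the input comparison, and 24% and 76% for the translation ratio. Of the unchanged simulated genes, 6, 6 and 4 were called in the 3 comparisons. The labels do not say whether replicates were grown, infected or treated separately, so p-values measure the spread between samples and no more.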

Results

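The data compare m6A peaks, RNA level and ribosome-bound RNA between METTL3 knockdown and control in HTR8/SVneo trophoblast cells under 30 mM glucose for 24 h. Input RNA (total RNA before precipitation) was sequenced in 2 control and 2 knockdown libraries, with 35000612 and 36466998 counts in control and 31474489 and 33470930 in knockdown. RNA from ribosome-nascent chain complexes (RNC RNA) was sequenced in 3 control libraries (39420561, 40889177 and 37796332 counts) and 3 knockdown libraries (38017482, 42115944 and 32667292). For the m6A precipitation, 2 control and 2 knockdown libraries are represented by peak lists, and their depth is unknown. Counts on mitochondrial genes made up 22.7% ± 4.4 of control and 17.0% ± 4.4 of knockdown RNC libraries (SD, n = 3 and 3), a difference with an exact two-sided permutation p of 0.2, where 0.1 is the smallest possible. In input RNA the shares were 9.0% ± 0.1 and 9.8% ± 0.7 (n = 2 and 2).

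METTL3, the catalytic subunit of the nuclear m6A methyltransferase (hg19 chromosome 14, 21966277 to 21979484), was measured first as a check of the labels. In RNC RNA it stood at 44.9, 36.3 and 42.4 CPM in the control libraries and at 10.4, 9.5 and 7.91 CPM in the knockdown libraries. That is 0.225 times the control level, a log2 fold change of −2.15 (SE 0.16, edgeR FDR 1.37e-06). In input RNA the control libraries had 59.6 and 48.1 CPM, and the knockdown libraries 41.3 and 16.3 CPM. Both knockdown values lay below both control values, but the log2 fold change of −0.90 (SE 0.39) did not pass the test (edgeR FDR 0.514).

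**Figure D1:**
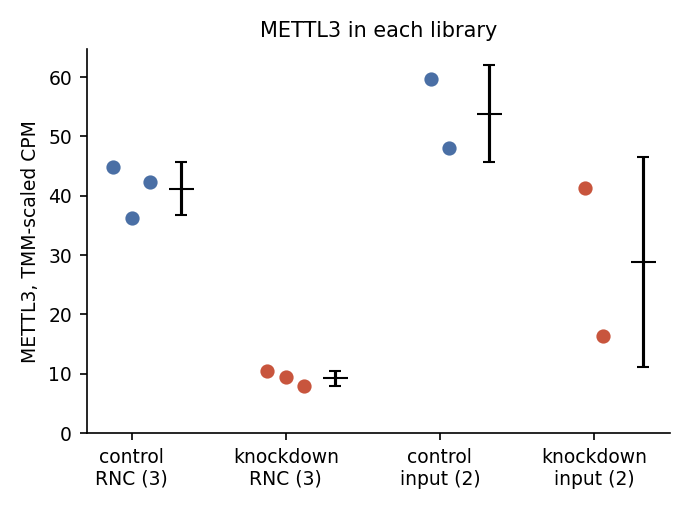
METTL3 in TMM-scaled CPM (vertical axis) in each RNC and input library, control in blue and knockdown in red; bars give the mean and SD. The knockdown RNC libraries lie between 7.91 and 10.4 CPM, whereas knockdown input replicate 1, at 41.3 CPM, lies close to the control libraries.

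The RNC comparison asks which transcripts changed in the ribosome-bound fraction after METTL3 knockdown. Among the leading rises, PSCA, a cell surface antigen, was 3.43 times the control level, H19, an imprinted non-coding RNA abundant in placenta, 3.25 times, and ALPP, placental alkaline phosphatase, 2.55 times. Among the leading falls, PRSS56, a serine protease, stood at 0.188 times control, IGFBP7, a secreted binding protein of insulin-like growth factors, at 0.337 times, and TGFBI, a matrix protein induced by TGF-beta, at 0.392 times. Of the fixed gene groups, heat shock proteins and translation factors were higher, and mitochondrial mRNAs, ribosomal proteins, invasion genes and glycolysis genes lower, by the test with a preset correlation. With an estimated correlation none of these 6 calls was kept (adjusted camera p from 0.407 to 0.83).

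Of 14281 genes tested, 1067 passed 5% FDR, 473 higher and 594 lower, and 3026 had an unadjusted p under 0.05. The knockdown and control libraries did not overlap for 3797 genes (26.6%, against 10% by chance). PSCA went from 22.1 ± 1.32 to 75.8 ± 7.01 CPM (SD, n = 3 and 3; log2 fold change 1.78, edgeR FDR 9.18e-07) and H19 from 380 ± 61.4 to 1230 ± 120 CPM (1.70, edgeR FDR 2.06e-06). The other leading rises were SUSD2, a membrane glycoprotein (1.51), ALPP (1.35, edgeR FDR 6.5e-06), HSPD1, the mitochondrial chaperonin (1.26), CTNNB1, the adhesion and Wnt signalling protein beta-catenin (1.18), the unnamed locus Z98256.1 (1.14), the cytokine receptor subunit IL20RB (1.09), the adipokine chemerin RARRES2 (1.09) and the proteasome subunit PSMA5 (1.06). PRSS56 showed the smallest p of all, from 1890 ± 185 to 354 ± 5.86 CPM (−2.41, SE 0.11, edgeR FDR 1.36e-08). ALPI, intestinal alkaline phosphatase, had a log2 fold change of −1.80, OLFML2A, an extracellular matrix protein, of −1.77, IGFBP7 of −1.57, RRBP1, a ribosome-binding protein of the endoplasmic reticulum, of −1.54 and ENO2, neuronal enolase, of −1.38. TGFBI (−1.35), the neutral amino acid transporter SLC1A4 (−1.35) and the type VII collagen gene COL7A1 (−1.25) completed the falls. ALPP and ALPI belong to 1 family of near-identical genes, so reads may be divided unevenly between them and their values are uncertain. All 20 leading genes, METTL3 among them, kept their direction and their call in each of 340 values under the alternatives. Their choice by large changes without overlap in the same libraries favours this. The number of calls fell to 517 without control replicate 1, 628 without control replicate 3, 553 without knockdown replicate 2 and 301 without knockdown replicate 3, and was 387 with all 10 libraries in 1 fit.

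The mitochondrially encoded mRNAs, which mitochondrial ribosomes translate, were lower as a group. Of 13 members 10 fell, 0 rose and 3 did not pass (0 higher and 11 lower adjusted over the list alone), and the median log2 fold change was −0.69. MT-ND3, a subunit of respiratory complex I, had −1.33 (edgeR FDR 0.00016) and MT-ND1 −0.78. The camera FDR was 1.4e-12, but the adjusted p was 0.407 with an estimated correlation. The share of all counts on mitochondrial genes moved with this group, as given above.

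Cytosolic ribosomal proteins shifted slightly downward, with a median of −0.12 over 76 members. Of these, 1 rose, 5 fell and 70 did not pass (1 and 5 adjusted over the list alone), among them RPL12 (−0.52), RPL18 (−0.46) and RPS15 (−0.45). The camera FDR was 0.000266, and the adjusted p was 0.83 with an estimated correlation. Without knockdown replicate 2 the camera FDR was 0.11 (median −0.08).

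Translation initiation and elongation factors moved the other way. Of 41 members 6 rose, 0 fell and 35 did not pass (11 higher and 1 lower adjusted over the list alone), with a median of 0.15. EIF2B1, a subunit of the exchange factor of eIF2, had 0.96, the poly(A)-binding protein gene PABPC1 0.72, and EIF3M and EIF3I, subunits of eIF3, 0.50 each. The camera FDR was 0.0234 and the adjusted p 0.407 with an estimated correlation. Without knockdown replicate 1 the camera FDR was 0.085, and with the mitochondrial share as a covariate it was 0.111, although the medians there, 0.14 and 0.18, were about as large.

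Heat shock proteins had a median of 0.45 over 13 members, of which 3 rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone). HSPD1 (1.26), the inducible chaperone HSPA1A (0.67) and HSPA4 (0.56) rose, and HSPB1, a small heat shock protein, fell by 0.55. HSPA1A shares reads with near-identical copies and is uncertain. The camera FDR was 0.000727, with an adjusted p of 0.407 with an estimated correlation.

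Genes of invasion and matrix remodelling were lower. Of 16 members 4 fell and 12 did not pass (0 higher and 7 lower adjusted over the list alone), with a median of −0.22: MMP2, a gelatinase (−0.84), the urokinase gene PLAU (−0.73), integrin ITGB4 (−0.62) and the urokinase receptor PLAUR (−0.47). The camera FDR was 0.000727, and the adjusted p 0.407 with an estimated correlation.

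Glycolysis and glucose transport genes had a median of −0.11. Of 25 members 1 rose, 2 fell and 22 did not pass (1 and 4 adjusted over the list alone). ENO2 (−1.38) and the glucose transporter SLC2A3 (−0.67) fell, and LDHB, a lactate dehydrogenase subunit, rose by 0.40. The camera FDR was 0.0234, the adjusted p with an estimated correlation was 0.789, and the camera FDR was 0.243 without control replicate 1 (median −0.06) and 0.0767 without knockdown replicate 3 (median −0.08).

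**Figure D2:**
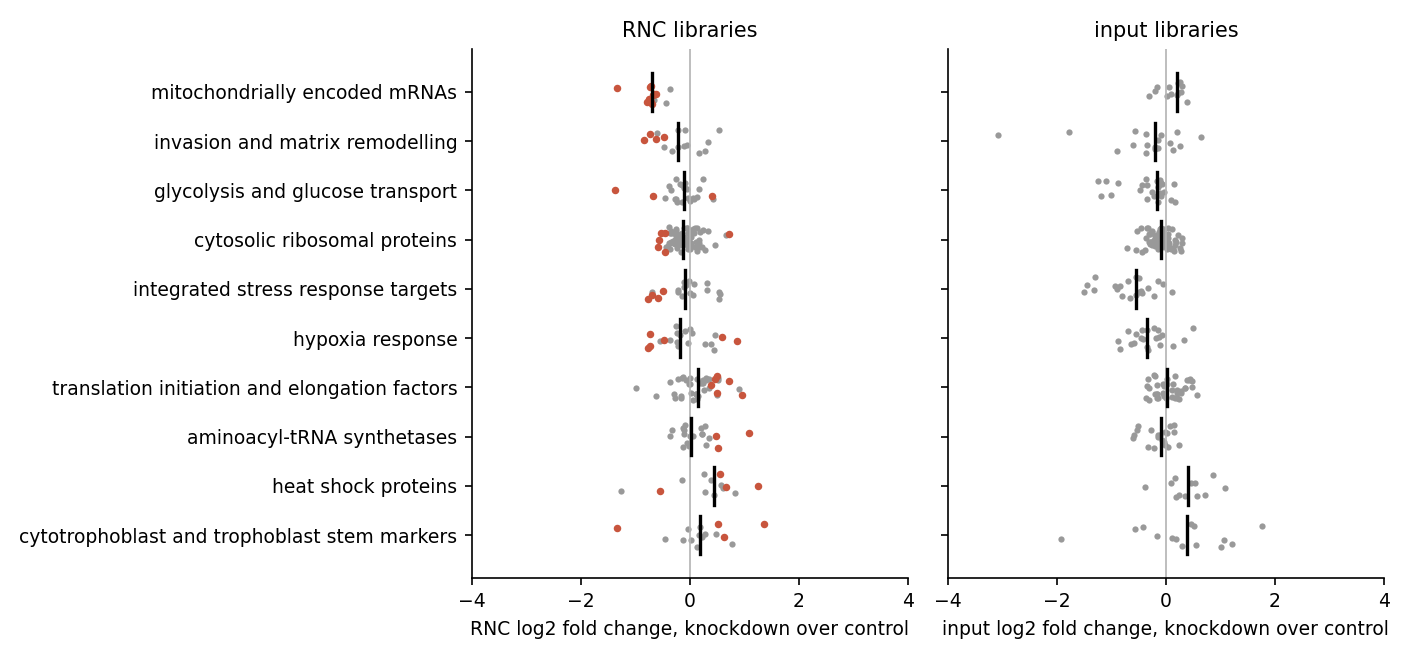
Log2 fold change of knockdown over control (horizontal axis) for each tested member of 10 gene lists, in RNC libraries (left) and input libraries (right). Red points passed 5% FDR and black lines are medians; the mitochondrially encoded mRNAs lie at a median of −0.69 in RNC and 0.21 in input RNA, and 1 member, ADAM12 in input RNA, lies outside the plotted range.

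The trophoblast markers did not pass as groups by camera. By fry the cytotrophoblast and trophoblast stem markers passed (adjusted fry p 0.000289), as the only RNC list. The RNC lists called by camera had adjusted fry p from 0.0535 to 0.568. Among cytotrophoblast and trophoblast stem markers, KRT7 (0.63), GATA2 (0.52) and TFAP2C (1.37) rose and SPINT1 fell by 1.34, with 11 of 15 not past (3 and 2 adjusted over the list alone, camera FDR 0.128). Of 5 syncytiotrophoblast markers, the pregnancy-specific glycoproteins PSG4 (0.73), PSG5 (1.42) and PSG1 (2.34) rose (3 and 0 adjusted over the list alone, camera FDR 0.13); they belong to a family of near-identical genes and their single values are uncertain. Of 13 extravillous trophoblast markers, PLAC8 rose by 0.80 and MMP2 fell by 0.84 (2 and 2 adjusted over the list alone, camera FDR 0.409). Stromal and mesenchymal markers had 1 rise, COL6A1 (0.83), and 2 falls, PDGFRB (−1.35) and COL5A1 (−0.64), among 16 (1 and 3 adjusted over the list alone, camera FDR 0.542). Of the endothelial markers 3 of 12 were tested, of the macrophage markers 2 of 16 and of the replication-dependent histone genes 3 of 55, too few for a test of each list. Their highest mean levels were 34.8 (the endothelial glycoprotein ENG), 7.23 and 5.7 CPM, and the only call was CSF1R, the receptor of a macrophage growth factor, at −0.92 (edgeR FDR 0.0155).

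In the stress and signalling lists single genes changed, and the group tests did not pass. Of 20 integrated stress response targets, NUPR1 (−0.76), PHGDH (−0.59), ATF3 (−0.70) and SHMT2 (−0.49) fell and 0 rose (0 and 5 adjusted over the list alone, camera FDR 0.0529). Cholesterol biosynthesis had 6 falls, among them INSIG1 (−0.79), the LDL receptor LDLR (−0.61) and SREBF2 (−0.46), and 1 rise among 23 (1 and 6 adjusted over the list alone, camera FDR 0.0514). In the p53 list of 19, CDKN1A (−0.76), BBC3 (−0.72) and 3 others fell and PLK2 rose by 1.12 (2 and 6 adjusted over the list alone, camera FDR 0.0983). Immediate-early genes had 5 falls, JUND (−0.83), IER3 (−0.65) and ZFP36 (−1.08) among them, and 1 rise, DUSP2 (0.63), among 15 (1 and 5 adjusted over the list alone, camera FDR 0.598). In the TGF-beta list of 20, TGFB1 itself was at −1.11 (edgeR FDR 1.65e-05), and ID2 and SMAD6 rose by 0.70 and 0.40 (2 and 1 adjusted over the list alone, camera FDR 0.523). Of 16 type I interferon genes, IFITM3 (−0.84), IFITM2 (−0.51) and IFI35 (−0.78) fell and MX1 rose by 1.77 (1 and 3 adjusted over the list alone, camera FDR 0.409). Of 21 hypoxia genes, 2 rose, among them EPAS1 (0.59), and 4 fell, among them P4HA1 (−0.73) and CA9 (−0.74), with 2 and 4 adjusted over the list alone and a camera FDR of 0.318.

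In the oxidative stress list of 24, TXNRD1 (0.63), CAT (1.02), GCLM (1.48) and 1 other rose and GPX4 fell by 0.43 (5 and 2 adjusted over the list alone, camera FDR 0.646). Nuclear-encoded oxidative phosphorylation had 3 rises, UQCRC2 (0.63), NDUFS1 (0.61) and ATP5A1 (0.41), among 33 (5 and 1 adjusted over the list alone, camera FDR 0.683). NARS (1.09), KARS (0.48) and IARS (0.52) rose among 20 aminoacyl-tRNA synthetases (3 and 1 adjusted over the list alone, camera FDR 0.36). Apoptosis regulators had 4 rises and 3 falls among 17 (5 and 3 adjusted over the list alone, camera FDR 0.409), with BID at 0.55 and BAD at −0.52. In the insulin and PI3K-AKT list of 25, PIK3R1 (1.77) and MTOR (0.50) rose and EIF4EBP1, a repressor of cap-dependent translation, fell by 0.43 (2 and 2 adjusted over the list alone, camera FDR 0.897). KIF23 (1.00) and CDK1 (0.68) rose among 28 mitosis genes (2 and 0 adjusted over the list alone, camera FDR 0.902), MCM4 (0.63) and RFC4 (0.49) rose and CCNE1 fell by 1.32 among 28 replication genes (2 and 1 adjusted over the list alone, camera FDR 0.786), and BECN1 (0.92) and LAMP2 (0.57) rose among 22 autophagy genes (3 and 1 adjusted over the list alone, camera FDR 0.902). NFKB1 rose by 1.03 as the only change among 12 inflammatory genes (1 and 0 adjusted over the list alone, camera FDR 0.754).

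For 2 further lists there was no call by edgeR at 5% FDR, with or without adjustment over the list alone: the 19 genes of the unfolded protein response (camera FDR 0.897) and the 15 SOX, KLF and other transcripts widely described as m6A-modified (camera FDR 0.646; MYC had a log2 fold change of 0.26). Of the m6A writer complex, METTL3 fell and KIAA1429 rose by 0.58 among 10 (1 and 1 adjusted over the list alone, camera FDR 0.902), and of 16 erasers and readers YTHDF2 rose by 0.86 (0 and 0 adjusted over the list alone, camera FDR 0.409). Median, mean and test differed in sign for extravillous markers, immediate-early genes, the insulin list, mitosis genes, inflammatory genes and the unfolded protein response.

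The input comparison asks which transcripts changed in total RNA. Among the genes chosen by the naming rule (past 5% FDR, with a symbol and a mean log2 CPM of at least 4), the largest rises were ALPP, at 8.75 times the control level, and H19, at 6.87 times, followed by UNC80, a subunit of the sodium leak channel complex, at 6.59 times and A2M, a secreted protease inhibitor, at 2.85 times. PRSS56 stood at 0.301 times control and TGFBI at 0.316 times. Integrated stress response, glycolysis and hypoxia genes were lower and heat shock proteins higher as groups, by the test with a preset correlation. None of these calls was kept with an estimated correlation (adjusted camera p from 0.384 to 0.409).

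By edgeR, 16 of 18528 genes passed 5% FDR, 8 higher and 8 lower, and 1739 had an unadjusted p under 0.05; 7350 genes (39.7%, against 33.3% by chance) had libraries that did not overlap. ALPP went from 55.1 ± 6.68 to 483 ± 2.9 CPM (SD, n = 2 and 2; log2 fold change 3.13, edgeR FDR 2.91e-05) and H19 from 161 ± 26.1 to 1100 ± 75 CPM (2.78, edgeR FDR 3.35e-05). UNC80 had 2.72, A2M 1.51, the transferrin receptor gene TFRC 1.37 and the sodium chloride cotransporter gene SLC12A3 1.35. The falls were PRSS56 (−1.73), TGFBI (−1.66), the actin regulator WIPF1 (−1.62), the focal adhesion protein TNS1 (−1.51), the membrane protein TM4SF1 (−1.48), COL7A1 (−1.40), RRBP1 (−1.23) and the collagen gene COL5A1 (edgeR FDR 0.0283). The 2 other rises carry Ensembl identifiers only: ENSG00000251562.3 (0.60) and ENSG00000224516.1 (3.88), which lies within ALPP on the opposite strand and cannot be told from it, since strand was not used in the counting. All 16 were called in each alternative but 1, which kept 15, while the total ranged widely: 354 with DESeq2, 252 with no filter, 54 with a filter of 1 CPM, 83 with limma-voom and 206 with all 10 libraries in 1 fit. Without single libraries it was 153 (control replicate 1), 420 (control replicate 2), 33 (knockdown replicate 1) and 29 (knockdown replicate 2).

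Among the lists, COL5A1, a stromal marker, was the only member called in input RNA. The test with a preset correlation called 10 of 30 lists, and none had an adjusted p under 0.05 with an estimated correlation. Integrated stress response targets had a median of −0.54 over 21 members, with 9 lower adjusted over the list alone (camera FDR 4.14e-11, adjusted p 0.384 with an estimated correlation); ASNS, asparagine synthetase, had a log2 fold change of −1.50. Glycolysis genes had a median of −0.16 over 25 (3 lower adjusted over the list alone, camera FDR 1.85e-07, adjusted p 0.384 with an estimated correlation), with ENO2 at −1.19 and the aldolase gene ALDOC at −1.25. Hypoxia genes had a median of −0.34 over 21 (0 adjusted over the list alone, camera FDR 0.000281, adjusted p 0.384 with an estimated correlation). Ribosomal proteins had −0.09 over 76 (1 lower adjusted over the list alone, camera FDR 0.000299, adjusted p 0.409 with an estimated correlation), aminoacyl-tRNA synthetases −0.09 over 20 (1 lower, camera FDR 0.00412, adjusted p 0.384 with an estimated correlation) and mitosis genes −0.16 over 29 (0, camera FDR 0.0178, adjusted p 0.384 with an estimated correlation). The invasion list had a median of −0.19 and a mean of 0.07 over 19 (1 lower, camera FDR 0.00717, adjusted p 0.384 with an estimated correlation).

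Heat shock proteins had a median of 0.41 over 12 members, with 6 higher and 1 lower adjusted over the list alone (camera FDR 1.85e-07, adjusted p 0.409 with an estimated correlation); HSPA1A stood at 1.09 and DNAJA1, a co-chaperone, at 0.71. The cytotrophoblast markers had 0.38 over 14, with 4 higher and 1 lower (camera FDR 0.000281, adjusted p 0.384 with an estimated correlation), among them the keratins KRT8 (0.55) and KRT18 (0.47) and GATA2 (1.02). Mitochondrially encoded mRNAs had a median of 0.21 over 13, with 5 higher and 1 lower (camera FDR 4.14e-06, adjusted p 0.409 with an estimated correlation), the opposite sign of their RNC change. Leaving out 1 library ended the calls of 5 lists. Without control replicate 1 the camera FDR was 0.0747 for invasion genes (median −0.16), 0.0604 for mitochondrial mRNAs (0.14) and 0.162 for mitosis genes (−0.15). Without control replicate 2 it was 0.0665 for invasion (−0.18), 0.0643 for mitosis (−0.17), 0.196 for aminoacyl-tRNA synthetases (−0.03) and 0.192 for ribosomal proteins (−0.07), and without knockdown replicate 2 it was 0.107 for invasion (−0.11) and 0.329 for mitochondrial mRNAs (0.05). The other 20 lists had camera FDR between 0.0968 and 0.991. By fry, only the cytotrophoblast markers (adjusted fry p 0.0396) and the m6A writer complex (0.0471) passed in input RNA. Median, mean and test differed in sign also for extravillous markers, immediate-early genes, inflammatory genes, stromal markers, the TGF-beta list and interferon genes.

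Changes in ribosome-bound RNA mostly had the same direction in total RNA. Of 464 genes higher in RNC RNA and tested in input, 364 (78.4%) were higher in input too, with a median log2 fold change of 0.25 against 0.72 in RNC; over all genes, 49.8% were higher. Of 587 lower genes, 488 (83.1%, against 50.2% of all genes) were lower in input, with a median of −0.34 against −0.61. As sets in the input libraries they had camera p of 3.9e-18 and 2.8e-25 over 4 libraries, from a model across all genes, and 0.0142 and 0.0158 with an estimated correlation. Across genes, which are not independent replicates, Pearson's r between the assays was 0.57 over the 1051 RNC calls and 0.16 over all 13668 genes. Of the 16 input calls 15 had the same sign in RNC RNA, UNC80 being the exception; 6 genes were called higher in both (0.27 by independent lists) and 8 lower in both (0.34).

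**Figure D3:**
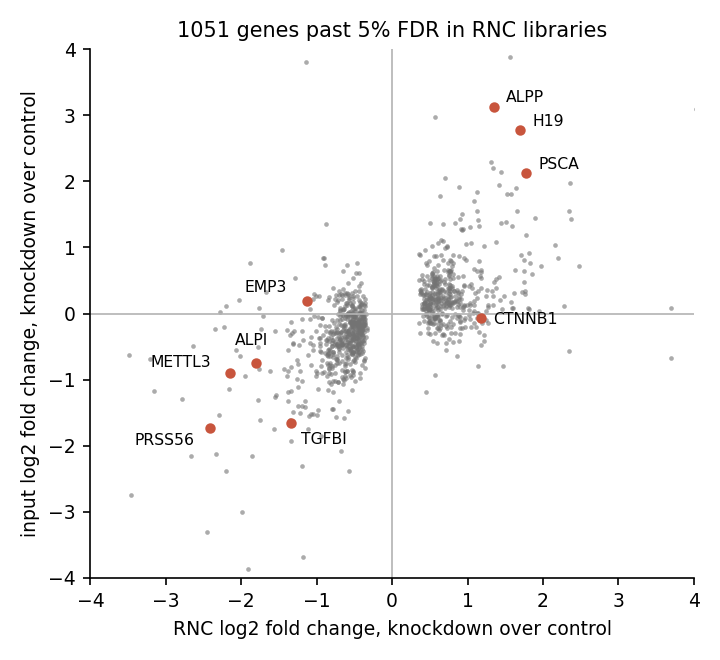
Log2 fold change of knockdown over control in input RNA (vertical axis) against RNC RNA (horizontal axis) for 1051 genes past 5% FDR in RNC RNA, 1 point per gene; 12 genes lie outside the plotted range. ALPP and H19 lie high in both, PRSS56 and TGFBI low in both, and CTNNB1 and EMP3 near 0 in input RNA.

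The translation ratio asks whether the RNC response exceeded the input response. EMP3, a membrane glycoprotein, went from 308 ± 17.8 to 141 ± 22.4 CPM in RNC RNA (SD, n = 3 and 3) with little difference in input RNA, where it had 42.5 ± 4.92 and 48.6 ± 1.44 CPM (n = 2 and 2); its log2 ratio was −1.33 (SE 0.20, edgeR FDR 0.0348). ALPP rose in both assays but less in RNC RNA, with a log2 ratio of −1.80 (SE 0.18, edgeR FDR 0.000829). METTL3 had a log2 ratio of −1.25, which did not pass (SE 0.41, edgeR FDR 0.37), and CTNNB1, which rose in RNC RNA alone, had 1.24 (edgeR FDR 0.0519).

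By edgeR, 4 of 19827 genes passed, all lower: ALPP, EMP3, ENSG00000224516.1 (−2.32), which cannot be told from ALPP, and ENSG00000268621.1 (−1.99), while 1910 had an unadjusted p under 0.05. For higher ratios edgeR called 0 genes, against 83 with DESeq2, 102 without a filter and 0 with limma-voom. EMP3 lost its call with limma-voom (FDR 0.215, log2 ratio −1.35) and without any 1 of 5 RNC libraries, although the ratio stayed about as large (−1.29, −1.29, −1.36, −1.28 and −1.24): the edgeR FDR was 0.147, 0.0871 and 0.0986 without control replicates 1, 2 and 3, and 0.131 and 0.222 without knockdown replicates 2 and 3, in a range over all alternatives from 2.21e-06 to 0.222. The number of calls was 41, 156, 36 and 39 (11, 47, 14 and 19 of them higher) without control input replicates 1 and 2 and knockdown input replicates 1 and 2, and 2, 2, 1, 8 (1 higher), 1 and 1 without control RNC replicates 1, 2 and 3 and knockdown RNC replicates 1, 2 and 3.

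As groups, the integrated stress response targets had a higher ratio, with a median of 0.54 over 21 members (1 higher adjusted over the list alone, camera FDR 0.00296, adjusted p 0.23 with an estimated correlation). Across its members the ratio varied: ASNS had −1.50 in input, 0.06 in RNC and a ratio of 1.55 (edgeR FDR 0.0889), and TRIB3, a pseudokinase of the same response, a ratio of 0.87, whereas PHGDH and SHMT2 had ratios of −0.17 and −0.03. Aminoacyl-tRNA synthetases, which charge tRNAs, had a median ratio of 0.25 over 20 members (0 adjusted over the list alone, camera FDR 0.00171, adjusted p 0.714 with an estimated correlation), with NARS at 1.03 and GARS at 0.54. Mitochondrially encoded mRNAs had −0.92 over 13 (10 lower adjusted over the list alone, camera FDR 1.11e-09, adjusted p 0.714 with an estimated correlation). The stress response call was lost without control input replicate 1 (camera FDR 0.0771, median 0.37), control input replicate 2 (0.0641, median 0.58) and knockdown input replicate 2 (0.0673, median 0.41), and the synthetase call without control input replicate 2 (0.0641, median 0.25). The other 27 lists had camera FDR between 0.214 and 0.968. By fry, only the integrated stress response targets passed for the ratio (adjusted fry p 0.0387). The sign of the test differed from that of the median or mean for extravillous markers, cholesterol genes, immediate-early genes, the insulin list, and erasers and readers.

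The peak comparison asks which called m6A peaks differed between knockdown and control. The control lists held 51232 and 59431 peaks and the knockdown lists 28421 and 28535, so the knockdown had 51.5% of the control number. With 2 libraries against 2, the exact two-sided permutation p was 0.333, the smallest possible. Peaks found in both replicates were more numerous in the knockdown, 20212 against 17172. The direction of the difference thus depended on what was counted. Bases covered were 92% of the control value, genes with an exonic peak 84.5% and peaks wider than 200 bp 126.3%. Of all peaks, 37.7% and 39.7% lay on exons in the control lists, against 53.5% and 53.9% in the knockdown lists. In the control lists 34.9% and 37.3% lay in introns only, and 27.5% and 22.9% outside genes. Among reproducible peaks the exonic shares were 59.8% in control and 58.5% in knockdown. Reproducible summits placed on exons of single coding genes numbered 7234 in control and 7688 in knockdown. Of these, 57.7% and 56.9% lay in the 3' part beyond the midpoint of exonic length, with no background share measured.

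Of 17172 reproducible control peaks, 84.6% overlapped a peak of at least 1 knockdown library (Wilson 95% interval 84.0 to 85.1%, counting error only), and 84.5% of reproducible knockdown peaks overlapped a control peak. Over all peaks of control replicates 1 and 2, reproducible or not, 39.8% and 35.8% overlapped a knockdown peak. Between replicates, 33.5% of the peaks of control replicate 1 were found in control replicate 2, and 71.1% of those of knockdown replicate 1 in knockdown replicate 2. After a shift of the control peaks by 10 kb, 6.0% overlapped a knockdown peak. In the authors' pooled lists, 29.9% of the control peaks overlapped a knockdown peak.

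**Figure D4:**
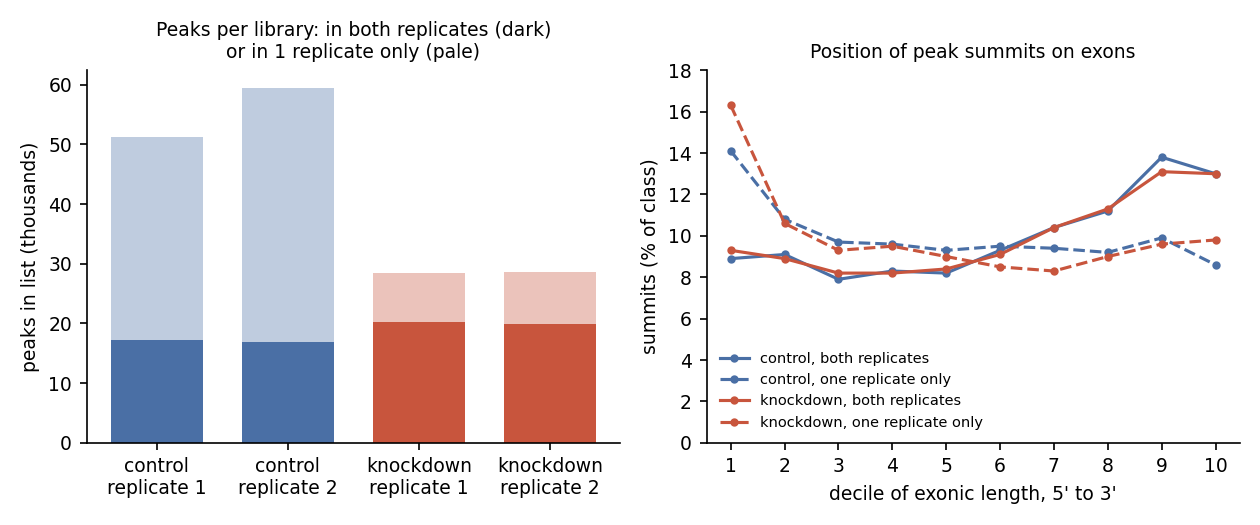
Left, number of m6A peaks per library, dark for peaks found in both replicates of a genotype and pale for peaks in 1 replicate. Right, share of exonic summits (percent) by decile of exonic length from 5' to 3'; reproducible peaks of both genotypes are most frequent in decile 9 (13.8% of control and 13.1% of knockdown summits), and peaks of 1 replicate in decile 1 (14.1% and 16.3%).

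By gene, 444 genes were m6A-lost, 408 gained (the same rule with the genotypes exchanged) and 6115 m6A-kept. Among genes with a mean input CPM of at least 1, 375 were lost and 180 gained, with median log2 input CPM of 5.2 and 1.91. With peaks wider than 200 bp the order at that level was reversed, with 107 lost and 694 gained. The number of lost genes was 120 with peaks wider than 200 bp and 3745 in the authors' pooled lists, where gained genes numbered 1067 and 1163. Among the genes of the m6A pathway itself, the writer subunit WTAP, both demethylases, FTO and ALKBH5, and the RNA-binding protein ELAVL1 were lost, whereas METTL3, METTL14, KIAA1429, RBM15, ZC3H13, CBLL1, METTL16 and the reader genes YTHDF1, YTHDF2, YTHDF3, YTHDC1, IGF2BP1, IGF2BP2 and IGF2BP3 were kept. Outside these classes, YTHDC2 and PRRC2A had a reproducible peak in the knockdown only, and RBMX in the control only. Ranked by the authors' fold enrichment in the pooled control list, a value comparable within that list only, the leading lost genes were VPS26A, a retromer subunit (fold 57.7, chromosome 10, 70883837 to 70884112), FANCC, of the Fanconi anaemia DNA repair pathway (57.5, chromosome 9, 97873778 to 97874578), DOCK6 (36.7), MORC4 (34.4), SEPT7 (31.4), SUMF1 (29.9), TTC21B (29.0), FAM96B (28.6, on a peak that also covers CES2), DNAJC13 (28.1) and NAA38 (27.7). The leading kept genes were C11orf30, a chromatin regulator (fold 594.6, chromosome 11, 76260933 to 76261710), FBXW7, a ubiquitin ligase subunit (355.1, chromosome 4, 153243346 to 153244395), MTFR1 (299.1), DSCR3 (268.3), WDR91 (261.4), AKAP2 (249.5), ZSCAN12 (247.4), ZNF41 (241.3), OGDH (236.3) and SHROOM3 (233.3). The peaks of the lost genes VPS26A, DNAJC13 and FAM96B, and of the kept gene SHROOM3, reach past the annotated 5' end of the gene. Their assignment to these genes is therefore less certain.

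Neither class passed 5% against other genes with a preset correlation. In RNC RNA the medians of lost and kept genes differed from those of other genes by −0.048 (camera p 0.292 over 6 libraries, from a model across all genes; 362 genes) and 0.018 (camera p 0.661; 5329 genes). In input RNA the differences were 0.028 (camera p 0.392) and 0.007 (camera p 0.892). For the translation ratio they were −0.112 (camera p 0.115) for lost and −0.006 (camera p 0.694, with a test sign opposite to the median) for kept genes. With an estimated correlation the lost genes' ratio had a camera p of 0.0355, or 0.213 after Benjamini-Hochberg adjustment over the 6 tests. The fry test, which does not compare with other genes, gave the lost genes an unadjusted p of 0.0261 in RNC RNA and 0.0199 for the ratio. In the remaining class tests the fry p lay between 0.197 and 0.571.

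Of genes tested in input RNA, 35.5% carried a reproducible control peak on exons. The share was higher among immediate-early genes (12 of 15, 80.0%), the m6A writer complex (8 of 10) and the erasers and readers (11 of 16, 68.8%), and lower among ribosomal proteins (6 of 76, 7.9%), nuclear-encoded oxidative phosphorylation (4 of 33, 12.1%), type I interferon genes (2 of 21, 9.5%) and mitochondrially encoded mRNAs (0 of 13), each past 5% FDR by Fisher's exact test with Benjamini-Hochberg adjustment (0.00819, 0.037, 0.0391, 1.28e-06, 0.037, 0.0481 and 0.037). Against random lists matched on expression and exonic length, immediate-early genes (37.8% expected, adjusted permutation p 0.006), ribosomal proteins (35.5%, 0.006) and oxidative phosphorylation (41.5%, 0.008) passed, and the other 4 did not. With the peaks of control replicate 2 alone (control replicate 1 left out), 4 lists passed. The other 23 lists had an adjusted Fisher p between 0.0505 and 1.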

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

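For the mitochondrial mRNAs, both tests described here were chosen only after the result was seen; the tests that marked the results of this part were planned. Each result stands here because the knockdown response in RNC RNA differed from that in input RNA in the interaction test (edgeR or camera, Benjamini-Hochberg).

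The log2 ratio was −1.80 for ALPP, −1.33 for EMP3, −2.32 for ENSG00000224516.1, whose exons lie inside ALPP on the opposite strand, and −1.99 for ENSG00000268621.1. Of these 4 gene calls only 1 was kept with limma-voom, and only 1 without control RNC replicate 3, knockdown RNC replicate 2 or knockdown RNC replicate 3. As groups, the integrated stress response targets had a median of 0.54, the aminoacyl-tRNA synthetases of 0.25 and the mitochondrially encoded mRNAs of −0.92. None of these 3 list calls was kept with an estimated correlation (adjusted camera p 0.23, 0.714 and 0.714).

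The mitochondrial mRNAs were lower in knockdown RNC libraries by a difference of medians of −0.73 log2 against an SD between libraries of the same genotype of 0.39. A lower amount of these transcripts in the knockdown cells would lower them in input RNA too, but their median there was 0.21, with 10 of 13 above 0, which argues against that explanation. The median was 0.05 without knockdown input replicate 2 and 0.14 without control input replicate 1, so a rise in input RNA is not established, but it was below 0 in none of the 4 fits that leave out 1 input library. What stays open is a different carry-over of mitochondria or mitochondrial ribosomes between RNC preparations, which may account for the shift. Between libraries of the same genotype the 13 mRNAs rose and fell together, with a median pairwise correlation of 0.96. Carry-over needs this, but any cause that acts on all 13 would give it too, so the correlation does not single out carry-over. A change in ribosome loading within mitochondria after METTL3 knockdown was not tested, and the share of counts on mitochondrial genes gave an exact two-sided permutation p of 0.2 where 0.1 is the smallest possible. The 6 RNC lists, of which this is 1, cannot be set against chance by regrouping either: the highest other split of the 6 libraries also gave 6 lists, and with 10 splits no share under 0.05 can be reached.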

How the results depend on the processing

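Chosen only after the data were seen were the alternatives on the mitochondrial share, peaks wider than 200 bp, peaks in both replicates, exonic peaks, each replicate left out of the peak number, and the peaks of 1 control replicate for list marking; the other tests were planned. All 20 leading RNC genes and 14 leading input genes kept their direction and their side of the threshold throughout. Of all values for named genes and lists, the leading genes included, 1995 were the same, 354 weaker, 41 stronger and 1 reversed. Of 1798 RNC values for named genes, 310 were weaker, none of them for the 20 leading genes. The leading genes had been chosen in the same libraries for large changes without overlap of the genotypes, which favours stable calls. The list members were chosen by another rule, so the 2 sets cannot be compared fairly for stability. The number of RNC calls was 903 (328 higher) without the 2 libraries of most extreme mitochondrial share and 1100 (430 higher) with that share as a covariate, against 1067 (473 higher). Like totals need not mean the same genes. Scaling moved the median log2 fold change of all genes by −0.04 at most.

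For the following values the cause was not tested, except where fewer libraries or other thresholds are the alternative itself. With all 10 libraries in 1 fit, 387 RNC and 206 input genes passed, against 1067 and 16. Input calls were also 354 with DESeq2, 252 with no filter, 54 with the filter of 1 CPM and 83 with limma-voom. Against 4 ratio calls there were 197 with DESeq2, 207 with no filter and 1 with limma-voom. With an estimated correlation, 0 lists passed in RNC, 0 in input and 0 in the ratio, against 6, 10 and 3.

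The m6A-kept genes changed sign in RNC RNA against matched genes (−0.02) and in input RNA with the authors' pooled lists (−0.001). For the ratio of the kept genes the median (−0.006) and the camera direction (up) differ in sign, and the sign used here is that of the median, a choice made after both had been seen. The ratio of the m6A-lost genes passed 5% before adjustment over the 6 tests with an estimated correlation (difference −0.112, camera p 0.0355) and against matched genes (−0.167, camera p 0.0215).

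The peak number of the knockdown, 51.5% of control, was 92% for bases covered, 84.5% for genes, 71.3% for exonic peaks, 126.3% for peaks wider than 200 bp, 117.7% for peaks in both replicates and 169.1% for wide peaks in both. The share of control peaks kept, 84.6%, was 85.6% at 50% overlap, 86% and 85.3% with a −log10 q of at least 5 in the control list and in both lists, 96.3% for wide peaks, 29.9% in the pooled lists, and 39.8% and 35.8% for all peaks of control replicates 1 and 2. Against matched random lists, 3 lists differed in marking, against 7.

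Leaving out each library in turn gave 301 to 1189 RNC calls, 29 to 420 input calls and 1 to 156 ratio calls, and 5 to 8, 7 to 11 and 1 to 5 lists. The lost genes' difference ranged from −0.057 to −0.039 in RNC, −0.003 to 0.083 in input (lowest without knockdown input replicate 1) and −0.124 to −0.073 for the ratio. For the kept genes it ranged from 0 to 0.023 in RNC, −0.026 to 0.042 in input (−0.003 without knockdown input replicate 1) and −0.048 to 0.049 for the ratio, where it was above 0 without control input replicate 2 (0.049), knockdown input replicate 1 (0.009), control RNC replicate 1 (0.01), and knockdown RNC replicates 1 (0.011) and 3 (0.004). CTNNB1 in input RNA ranged from −0.15 to 0.01. The peak number ranged from 47.9% to 55.6%, the kept share was 79.8% without either knockdown replicate, and 4 to 9 lists differed in marking. In the input fits that leave 1 library in a group, that library is assumed to vary like the others.

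With the replicate number as a block, 966 RNC, 143 input and 5 ratio genes passed (without it 1067, 16 and 4), and 6, 10 and 3 lists, as without it. The numbers were not taken to pair the samples: 0 of 3 control RNC libraries and 2 of 2 control input libraries correlated best with the knockdown library of the same number, the latter at an r of 0.04 only. The test of m6A enrichment per gene and the sequence at peaks were not run. Of simulated 2-fold changes, 45% were found in input RNA with 2 libraries against 2 and 24% in the ratio with 10 libraries, so an absent call there says little, and for the peaks an unknown depth limits every comparison.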

Other observations

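The tests on the peak lists and on a mixture of cells in the input replicate were chosen only after the result was seen, as were the neighbours of ALPP; the comparison of the METTL3 gap with other genes and the regroupings of the libraries were planned.

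Genes beside ALPP on the long arm of chromosome 2 moved in opposite directions, described here after their values were seen. ALPP, placental alkaline phosphatase (hg19 chromosome 2, 233243434 to 233247319), rose by 1.35 log2 in RNC RNA, while ALPI, the intestinal isoenzyme (233320835 to 233323994), changed by −1.80. PRSS56, a serine protease (233385173 to 233390422), changed by −2.41, and its neighbour CHRND, the delta subunit of the muscle acetylcholine receptor (233390703 to 233401377), by −2.33 (SE 0.42, edgeR FDR 0.00398), from 3.79 ± 0.467 to 0.746 ± 0.316 CPM (SD, n = 3 and 3). In input RNA, CHRND had a log2 fold change of −2.13 (edgeR FDR 0.463). ALPP and ALPI are close paralogs, so the split of reads between them is uncertain, and no test of a shared cause was made.

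UNC80, a subunit of the sodium leak channel complex, was 146 ± 23.5 CPM in knockdown input RNA against 22.1 ± 3.23 in control (SD, n = 2 and 2) but only 0.548 ± 0.429 and 0.571 ± 0.594 CPM in RNC RNA (n = 3 and 3). Its log2 ratio was −2.78 (SE 0.81, edgeR FDR 0.32), so the difference between the assays did not pass the test. ENSG00000251562.3, which the count tables do not pair with a symbol, rose in input RNA as well (log2 fold change 0.60, edgeR FDR 0.00798).

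In the pattern of shorter knockdown peak lists, if the surplus of control peaks were calls found in 1 control library only, the reproducible peaks would not be fewer in the knockdown, and their number was 117.7% of that of the control. That value was known before the test and only divides the same lists. In these lists the surplus did lie in calls of 1 library: 34060 and 42464 in control against 8209 and 8552 in knockdown. Peaks found in both replicates numbered 17172 and 16967 in control against 20212 and 19983 in knockdown. Why the calls of 1 control library arose was not tested and stays open. If the knockdown had fewer m6A sites, reproducible control peaks would be found less often in the knockdown lists than the reverse; the shares differed by −0.1 percentage points, and for peaks wider than 200 bp 96.3% of control peaks were found in knockdown against 73.8% in reverse (found in both other libraries, all widths: 75.0% against 59.3%). These values do not settle the question, because the depth and sensitivity of the precipitated libraries are unknown, and nor does the authors' fold enrichment, whose median over reproducible peaks was 13.52 and 11.67 in control and 9.41 and 9.47 in knockdown (median −log10 q 226.1 and 189.0 against 71.2 and 74.8), since these values can depend on depth as well. Peaks at the 200 bp minimum made up 67.4% and 68.4% of the control lists against 20.6% and 21.9% of the knockdown lists, so the lists also differ in the shape of the calls.

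METTL3 itself stood at 41.3 CPM in knockdown input replicate 1 and 16.3 in replicate 2, against 59.6 and 48.1 in the control libraries. A mixture with control cells or RNA would need a control share of 66.5% and would leave 33.5% of the response of other genes. Over 814 genes called in RNC RNA, the response in replicate 1 was 1.02 times that in replicate 2 (95% bootstrap interval over genes 0.94 to 1.10), which argues against a mixture. Ordinary spread between input libraries is argued against too, since the METTL3 gap lay at percentile 99.7 of 2192 genes of like level. Whether the replicates differ in knockdown efficiency for this transcript was not tested, and the culture history of the replicates is not given.

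Regrouping the 6 RNC libraries gives 10 splits, too few for a share under 0.05. The real split gave 1067 genes past 5% FDR (1 of 10 splits gave as many), and the highest of the others gave 1. Every other split mixes the genotypes within each group, so a genotype difference widens the spread there and lowers the calls. The low numbers of the other splits are therefore no chance level for 1067. For the m6A-lost genes the camera p in RNC RNA was 0.292 in the real split (1 of 10 gave one as small) and 0.402 at the lowest in the others. For the m6A-kept genes it was 0.661 (7 of 10) and 0.104. As many lists as in the real split, 6, were found in 2 of the 10 splits.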
